A study of Rattus norvegicus with 9 samples.

How the data were processed

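The series holds 9 one-colour microarrays, 1 per rat, in 3 groups of 3 that the sample titles define (blank, model and electroacupuncture). The series text counts 3 animals per group and calls them mice, while the organism and the sample labels say rat. Per the labels' protocols, total RNA was digested with RNase R, amplified and labelled with Cy3 by random priming with an Arraystar kit.

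Per the file headers, spot intensity was read with Agilent Feature Extraction 11.0.1.1, and the deposited processed signal is an intensity on a linear scale, background-subtracted and detrended within each array and not normalized between arrays. The median spot and background intensities and the quality flags were taken from the same files as deposited. The deposited series matrix holds log2 values of 14145 circRNA probes. Their column medians were 6.06 (blank 1), 6.068 (blank 2), 6.081 (blank 3), 6.068 (model 1), 6.06 (model 2), 6.068 (model 3), 6.056 (electroacupuncture 1), 6.079 (electroacupuncture 2) and 6.055 (electroacupuncture 3), and each column's rank correlation with that array's median spot intensity was at least 0.9939. How those values were centred is unknown here. The submitters' processing notes also name limma, with no role given. All 9 columns of the matrix were matched to samples.

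Each file held 15701 spots, of which 15165 were not controls, for 14227 probes. These were 14145 circRNA probes with 1 spot each, 62 probes with an accession of a linear transcript and 10 spots each, and 20 probes without an accession and 20 spots each. Control spots and outlier-flagged spots (36 to 117 per array) were left out, no spot was saturated, and the spots of a probe were averaged. The median SD of the spots of 1 linear probe on 1 array was 0.081 on the log2 scale. Accessions were matched without versions to RefSeq gene names of the rat assembly GRCr8, used only for names. The matching gave a symbol to 39 of the 62 probes, or 38 genes, and the others keep the name in the files. Whether the linear probes also bind circular forms of their genes is not given in the sources used here.

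Values were log2 processed signals minus each array's 75th percentile over all non-control probes. That percentile ranged from 71.3 (blank 1) to 189.7 (model 2) on the linear scale, and 82.6% of probes were well above background on average. A probe was kept if it was well above background on every array of at least 1 group, which left 11338 probes, of which 11297 were circRNA probes and 35 were linear. A probe not well above background on some arrays of a group is named with their number. No pair of arrays held identical values.

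Group means were fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), and the 3 contrasts were tested with eBayes at a Benjamini-Hochberg adjusted p under 0.05 over all kept probes. The 35 linear probes, which average 10 spots, were fitted and adjusted on their own. That step was added after the data were seen, and over all kept probes their lowest adjusted p was 0.167, 0.994 and 0.146 in model against blank, electroacupuncture against model and electroacupuncture against blank. A count with an unadjusted p under 0.05 and at least 1.5-fold was kept as a description. Exact permutation of 3 against 3 arrays cannot give a p below 0.10.

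The planned rule named the 10 widest differences per direction among probes past the test, filled up by the lowest p, together with the circRNA in the series title and circRNAs of host genes in 18 fixed lists. The files used here do not pair the probe identifiers with circRNA names, host genes or positions. The named circRNA and the list tests therefore have no value, and 1 probe identifier per direction is given for 2 comparisons. Of the fixed lists, 4 had a tested gene among the linear probes, none with more than 3.

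The fit was tested on simulated data for 11297 probes. In model against blank, 22% of probes changed 2-fold and 90% of those changed 4-fold were recovered, and unchanged data gave 0 calls. The simulated noise was independent between probes, with no factor acting on whole arrays, and the same simulated arrays held changes of 8-fold and 16-fold. These shares therefore do not tell what share of such changes the real arrays would have given. Alternatives covered scaling, background correction, the deposited values, the filter on dim probes, flagged spots, blocks for replicate number and scan day, the variance model, array weights, the samples in the fit and leaving out each array, with the filter applied again to the arrays left. A fit with electroacupuncture replicate 2 left out and the probes of the main fit was added after the data were seen. A mean spot signal was not in the files, so the planned normexp correction used the median signal. Array position does not repeat within a scan day, so a block for slide apart from scan day was not run. Choices not named here or below as added or chosen after the data were seen were made before the data were examined.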

Results

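RNA left after RNase R, an exonuclease that degrades linear RNA and spares circles, was measured in brain tissue from the territory of the middle cerebral artery of male rats aged 8 weeks. The arrays covered 3 groups of 3 rats. The blank group had the operation without the suture and no stimulation. The model group had permanent occlusion of the right middle cerebral artery by an intraluminal suture. The electroacupuncture group had the same occlusion, followed at once by stimulation of the Shuigou acupoint below the nasal septum at 15 Hz and 2 mA for 20 min. The labels placed both occluded groups at day 1. Each array carried 14145 probes for circular RNAs (circRNAs), which are closed RNA loops made by back-splicing, and 62 probes with accessions of linear transcripts. The share of circRNA probes well above background ranged from 59.2% in blank replicate 2 to 98.9% in electroacupuncture replicate 1. The number of arrays limited the precision. The series names a circRNA, rno_circ_011971, with the cilium gene Arl13b and the VEGF receptors, but the sources used here do not pair the probe identifiers with circRNA names or host genes, so no value is given for any of them.

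The blank arrays were the group most like each other. Their rank correlations over the 11297 circRNA probes kept for testing were 0.94 to 0.982, against 0.86 to 0.947 among model arrays and 0.773 to 0.919 among electroacupuncture arrays. The first principal component held 49% of the variance and placed the blank arrays at -44.1, -47.2 and -30.3 and the model arrays at 12.3, 54.7 and 14.8. Electroacupuncture replicates 1 and 3 lay at 57.1 and 25.2, and replicate 2 lay at -42.5. The arrays with the highest scores also had the highest 75th percentiles of signal. These were 186.3 in electroacupuncture replicate 1, 189.7 in model replicate 2 and 137.4 in electroacupuncture replicate 3. Model replicate 3, with 75.52, lay at 14.8, above all blank arrays. Whether this component follows array signal as well as group was not tested. The second component, with 16.6%, placed electroacupuncture replicate 2 at -51.7, below the other 8 arrays.

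**Figure D1:**
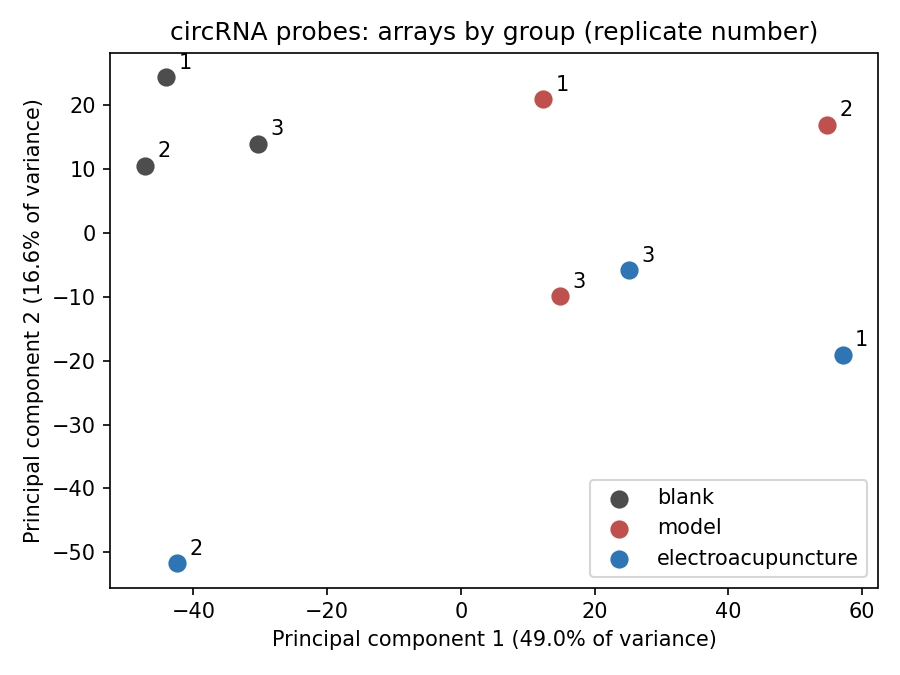
Principal components 1 and 2 (scores, no unit) of log2 signals of circRNA probes, 1 point per array, coloured by group and numbered by replicate. Electroacupuncture replicate 2 lies at -42.5 on component 1, within the range of the blank arrays, and at -51.7 on component 2.

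The comparison of model with blank addressed what occlusion did to the RNase R-resistant RNA of the territory. The log2 signal of Rpl13a, which encodes a protein of the large ribosomal subunit, was -2.26 ± 0.26 in blank and -0.73 ± 0.39 in model (SD, n = 3 each), a difference of 1.53 with a standard error of 0.47, and the probe was well above background on 2 of the 3 blank arrays. Standard errors here rest on the spread within all 3 groups, not within blank and model alone. The SD of Rpl13a in electroacupuncture tissue was 0.99. The difference was 1.00 (SE 0.62) for Rplp1, an acidic ribosomal protein, and 0.98 (SE 0.38) for Eif4b, an initiation factor, likewise well above background on 2 blank arrays. Both probes of Ldha, the lactate dehydrogenase subunit that favours lactate formation, had higher means in model, by 1.03 (SE 0.44) and 1.64 (SE 0.82). Pdk3, a kinase that inhibits pyruvate dehydrogenase, had a lower mean in model, with a difference of -1.13 (SE 0.39). With normexp background correction of the median signals the differences were 0.46 for Rpl13a, 0.73 for Rplp1, 0.12 for Eif4b, 0.60 and 1.00 for the Ldha probes and -0.58 for Pdk3. Leaving out 1 array moved Rplp1 between 0.66 and 1.55. Pgk1, another glycolytic enzyme, differed by 0.16 (SE 0.35), within its spread, and by 0.01 to 0.41 when 1 array was left out.

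None of these differences passed limma's test after Benjamini-Hochberg adjustment over the 35 linear probes tested. The adjusted p was 0.12 for Rpl13a, 0.16 for Pdk3, 0.17 for Eif4b, 0.17 and 0.22 for the Ldha probes and 0.33 for Rplp1. The hypoxia and glycolysis list, fixed before the data were examined, had 3 measured genes here (Ldha, Pgk1 and Pdk3) and none passed. Slc28a2, a nucleoside transporter, had a mean 0.96 higher (SE 0.40) with an adjusted p of 0.17, and 0.41 higher with normexp. Fgf2, an angiogenic growth factor and the 1 measured gene of the angiogenesis list, had a mean 0.56 higher (SE 0.34) with an adjusted p of 0.33, and 0.01 higher with normexp. It was well above background on 2 blank arrays. Map2, a microtubule protein of dendrites and the 1 measured gene of the neuronal marker list, differed by 0.01 (SE 0.34), and its sign changed in some settings. Dlg4, the scaffold of excitatory postsynapses, differed by -0.38 (SE 0.80), with the opposite sign in 1 setting. Sdha, a subunit of succinate dehydrogenase, differed by -0.26 (SE 0.22), and Hsp90ab1, a cytosolic chaperone, by -0.20 (SE 0.20). Leaving out model replicate 3 reduced them to -0.11 and -0.13, and normexp to -0.12 and -0.07. The widest difference among linear probes was on a transcript left without a symbol (ENSRNOT00000072358), at 2.64 (SE 0.80) and an adjusted p of 0.12. In all, 27 of the 35 linear probes had higher means in model and 8 had lower means, and 10 had an unadjusted p under 0.05 with at least 1.5-fold. That count was 1 with normexp, where the median difference was 0.014 in place of 0.361, 5 with scan day as a block, 14 with array weights, and 3 (without blank replicate 1 or model replicate 3) to 17 (without electroacupuncture replicate 2, 46 probes tested) when 1 array was left out. These genes were named after their values were seen, since the planned rule concerned circRNAs.

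**Figure D2:**
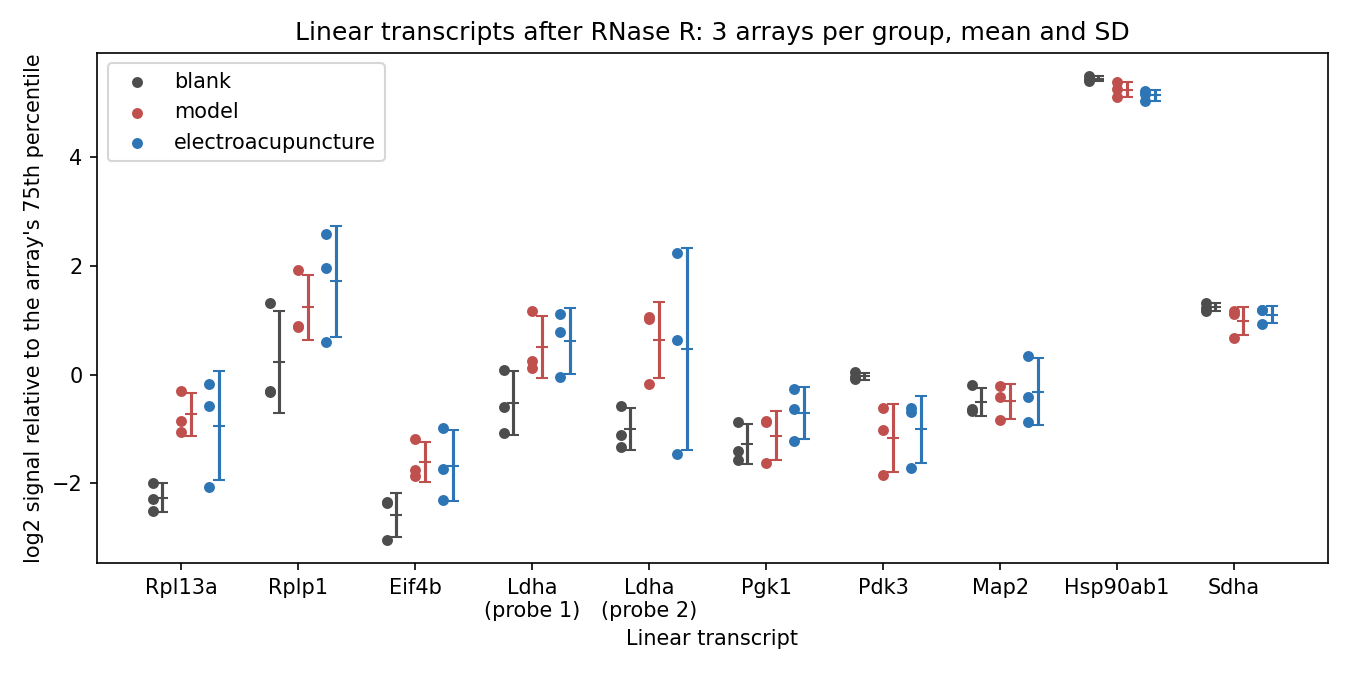
Log2 signal relative to each array's 75th percentile (y axis) of 10 probes for linear transcripts (x axis) in blank, model and electroacupuncture tissue; points are the 3 arrays of a group, and the bar beside them is the mean with the SD. Rpl13a was -2.26 in blank and -0.73 in model on average, and Map2 was -0.50 and -0.49.

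Among circRNA probes, limma called 0 of 11297 in model against blank, with a lowest adjusted p of 0.157. At an unadjusted p under 0.05 there were 2542 probes, where 565 would be expected by chance. With at least 1.5-fold as well there were 2315 probes, 1416 higher and 899 lower in model. With quantile normalization the split was 1063 higher and 803 lower, and with the deposited values 620 higher and 609 lower. Among probes well above background on all 9 arrays it turned to 728 higher and 833 lower, and among the 3766 brightest probes it was 372 and 390. The 3 model arrays lay entirely above or below the 3 blank arrays at 40.2% of probes, against the mean of 10% over all splits, from which 1 split can lie far. The higher probe with the lowest p was ASCRPR002193, at -4.35 ± 0.42 in blank and -2.15 ± 0.27 in model (SD, n = 3), and it was well above background on 1 blank array and on 3 model arrays. Its difference of 2.19 was 0.16 with normexp and 0.54 with the deposited values. The lower probe with the lowest p was ASCRPR003351, at 5.04 ± 0.69 in blank and 2.61 ± 0.60 in model. Their adjusted p was 0.157 in both cases. With electroacupuncture replicate 2 left out and the same probes tested, 519 circRNA probes and 11 of the 35 linear probes passed, among the latter Rpl13a, Slc28a2, Eif4b and 1 of the 2 Ldha probes (adjusted p 0.045, and 0.072 for the other). With the filter applied again to the arrays left, 222 of 12410 circRNA probes and 12 of 46 linear probes passed, and Eif4b no longer did (adjusted p 0.062, against 0.048 with the same probes). Of these 12, 3 were not among the 35, namely Gusb, which was well above background on 1 blank array and 2 model arrays, and 2 transcripts without a symbol. With the model and blank arrays alone in the fit 257 circRNA probes and 11 linear probes passed, and with array weights 3031 and 12. The weight was 3.22 for model replicate 1 and 0.57 and 0.475 for model replicates 2 and 3, so the weighted fit leaned on 1 model array. Adjusted over all kept probes, the linear counts without electroacupuncture replicate 2 became 4 with the same probes and 2 with the filter applied again. They became 2 with the model and blank arrays alone and 13 with array weights.

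The comparison of electroacupuncture with model addressed what stimulation added to occlusion. The named linear transcripts had no difference past the test, and the lowest adjusted p over the 35 probes was 0.874. Ndfip1, an adaptor of Nedd4-type ubiquitin ligases, was -1.76 ± 0.21 in model and -0.94 ± 0.37 in electroacupuncture tissue (SD, n = 3 each), a difference of 0.82 (SE 0.36). B2m, the light chain of class I histocompatibility molecules, differed by 1.04 (SE 0.64), and Trim2, a ubiquitin ligase of neurons, by 0.68 (SE 0.31). With normexp these 3 differences were 0.36, 0.52 and 0.22, and leaving out 1 array moved B2m between 0.47 and 1.65 and Trim2 between 0.45 and 0.82. Dlg4 differed by 0.84 (SE 0.80), which came from electroacupuncture replicate 2 at 2.49, against -0.44 and -0.15 in the other two, and without that replicate the difference was -0.09. Pgk1 differed by 0.41 (SE 0.35) and Fgf2 by 0.19 (SE 0.34), with ranges of 0.16 to 0.67 and 0.00 to 0.51 when 1 array was left out. Rpl13a differed by -0.21 (SE 0.47), Eif4b by -0.08 (SE 0.38), and the Ldha probes by 0.11 (SE 0.44) and -0.16 (SE 0.82). The signs of these last 4 differences changed between settings, while Ndfip1, B2m and Trim2 were higher in every setting run. The settings share the same arrays, and these genes were named after their values were seen, so a steady sign is no separate evidence. Of the 35 linear probes, 19 had higher and 16 had lower means than in model. Only 1 had an unadjusted p under 0.05, where 2 would be expected by chance.

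For the circRNA probes, limma called 0 of 11297, with a lowest adjusted p of 0.994. The 540 probes at an unadjusted p under 0.05 compare with 565 expected by chance. With at least 1.5-fold as well there were 496 probes, 465 higher and 31 lower in electroacupuncture tissue. Simulated arrays without any difference, and with noise independent between probes, gave 484. Quantile normalization split such probes into 178 higher and 151 lower, and scaling to the median into 240 higher and 191 lower. The median difference of all kept circRNA probes moved from 0.039 to -0.11 with scaling to the median. The arrays of the 2 groups did not overlap at 8.37% of probes, against the mean of 10% over all splits. ASCRPR010295 was -2.82 ± 0.32 in model, where 2 arrays were well above background, and -0.96 ± 0.66 in electroacupuncture tissue, and its difference of 1.86 was 0.68 with normexp, 0.98 with the deposited values and 1.25 with array weights. ASCRPR005854 was 5.88 ± 0.89 in model and 3.75 ± 1.11 in electroacupuncture tissue, and its difference of -2.13 was -1.10 without the arrays of the earlier scan day. Both had an adjusted p of 0.994. In simulated data for this comparison, 22% of probes changed 2-fold and 86% of those changed 4-fold were recovered among 11297. That simulation held no factor acting on whole arrays, so the shares do not carry over to the real arrays. The 496 probes became 191 without model replicate 1, 826 without electroacupuncture replicate 1 and 777 without electroacupuncture replicate 3, each with the filter applied again, and the call count stayed at 0 in each.

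Across circRNA probes, the model-minus-blank and electroacupuncture-minus-model differences had a Pearson correlation of -0.438, over probes that are not independent replicates. Both differences contain the model arrays with opposite signs, and simulated unchanged groups gave -0.50. The covariance was -0.123 against -0.0677 in the simulation. Without electroacupuncture replicate 2 the correlation was 0.119. Of the 1416 probes higher in model than in blank, 1015 had the opposite sign in electroacupuncture against model, and 23 of these passed the unadjusted p and fold there. Of the 899 lower probes, 782 had the opposite sign and 80 passed. These probes were picked on the same model arrays, which favours opposite signs without any effect of stimulation, and no share for unchanged groups is given here. The model arrays cannot be divided into parts of at least 2, so how much of these values comes from the shared arrays cannot be told. The counts are no evidence of a reversal.

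The comparison of electroacupuncture with blank joined occlusion and stimulation. The difference was 1.32 (SE 0.47) for Rpl13a, 1.48 (SE 0.62) for Rplp1, 1.14 (SE 0.44) and 1.48 (SE 0.82) for the Ldha probes, 0.90 (SE 0.38) for Eif4b and 0.91 (SE 0.31) for Trim2. Rpl13a, Eif4b, Trim2 and Fgf2 were well above background on 2 of the 3 blank arrays. Pdk3 had a difference of -0.97 (SE 0.39). The adjusted p was 0.15 for Rpl13a, Rplp1, Eif4b, Trim2, Pdk3 and the first Ldha probe, and 0.25 for the second. Fgf2 had a mean 0.76 higher (SE 0.34) with an adjusted p of 0.16. With normexp the differences were 0.45 for Rpl13a, 0.13 for Eif4b, 0.10 for Trim2, 0.11 for Fgf2, 1.22 for Rplp1, 0.74 and 1.07 for the Ldha probes and -0.55 for Pdk3. Leaving out 1 array moved the second Ldha probe between 0.59 (without electroacupuncture replicate 1) and 2.44 (without electroacupuncture replicate 2), Eif4b between 0.56 and 1.21 and Pdk3 between -1.17 and -0.62. Of the 35 linear probes, 29 had higher and 6 had lower means than in blank.

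Limma called 0 of 11297 circRNA probes in electroacupuncture against blank, with a lowest adjusted p of 0.0667 and 2234 probes at an unadjusted p under 0.05. With at least 1.5-fold as well there were 1992 probes, 1524 higher and 468 lower. That total was 366 with normexp. With 1 array left out and the filter applied again, it was 1126 (without electroacupuncture replicate 1) to 4304 (without electroacupuncture replicate 2). Quantile normalization gave 695 higher and 637 lower, and scaling to the median 874 higher and 1207 lower. The median difference of all kept circRNA probes was 0.168, against -0.005 with quantile normalization and -0.054 with scaling to the median. The groups did not overlap at 26.6% of probes, against the mean of 10% over all splits, from which 1 split can lie far. With electroacupuncture replicate 2 left out and the same probes tested, 1184 circRNA probes passed, 986 higher and 198 lower, and 17 of the 35 linear probes passed, including Rpl13a, Rplp1, both Ldha probes, Eif4b, Slc28a2, Fgf2 and Trim2, each higher. With the filter applied again, 1133 of 12410 circRNA probes and 24 of 46 linear probes passed, and 7 of the 24 were not among the 35. Adjusted over all kept probes, the 17 became 10 and the 24 became 12. Array weights, which gave electroacupuncture replicate 2 the lowest weight of 0.212, called 4161 circRNA and 19 linear probes (21 over all kept probes). Model replicate 1 had a weight of 3.22 and electroacupuncture replicate 3 one of 3.14, against 0.212 to 0.57 in the other occluded arrays. That fit therefore leaned on 1 array in each occluded group. With the filter applied again, 4 circRNA probes passed without blank replicate 2 and 1 without model replicate 2.

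The correlation of the model-minus-blank with the electroacupuncture-minus-blank differences was 0.799, against 0.499 in simulated unchanged groups that shared the blank arrays. The covariance was 0.334, against 0.0676 in the simulation. The simulation was matched to the spread of single probes. Any factor that acts on whole arrays and separates blank from occluded arrays, such as array position, would also raise both values. They therefore do not single out occlusion.

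Arrays were scanned on 2 days. The earlier day held model replicate 3 and electroacupuncture replicate 1, too few for a test within it, and the later day held the other 7 arrays. With scan day as a block, limma called 0 circRNA probes in each comparison, and the probes past the unadjusted p and fold numbered 1515 in model against blank, 474 in electroacupuncture against model and 1406 in electroacupuncture against blank. Within the later day these counts were 2544, 783 and 1125, again with 0 calls. The Rpl13a, Ldha and Pdk3 differences between model and blank had the same sign in every setting run. On the later day the blank arrays lay in 1 row of array positions and the occluded groups in the other, so array position and occlusion cannot be told apart there.

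**Figure D3:**
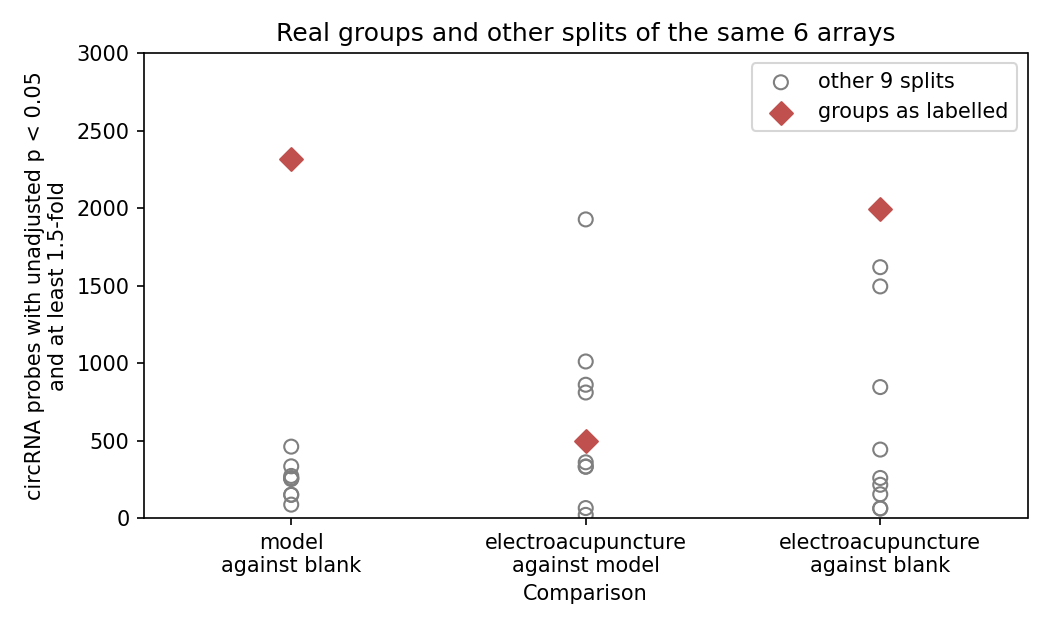
Number of circRNA probes with an unadjusted p under 0.05 and at least 1.5-fold (y axis) in each comparison (x axis), for the groups as labelled (diamond) and for the other 9 splits of the same 6 arrays (circles). The labelled groups gave 2315, 496 and 1992 probes, and the highest other splits gave 462, 1927 and 1619.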

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

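The normexp correction on median signals, the fit without the earlier scan day, the fit of the main probes without electroacupuncture replicate 2 and the linear probe results were chosen after the data were seen. The call count of 0 circRNA probes in electroacupuncture against model held in every setting run. The other 2 call counts left 0 with array weights (3031 in model against blank and 4161 in electroacupuncture against blank), with only the 2 groups compared (257 in model against blank) and with the percentile over probes above background on all arrays (1 in electroacupuncture against blank). The weighted fit leaned on 1 array in each occluded group, as given above. Linear probe calls left 0 with array weights (12 and 19, in the same order) and with only the 2 groups compared (11 in model against blank). Adjusted over all kept probes these linear counts were 13, 21 and 2. Leaving out 1 array gave 0 to 222 and 0 to 1133 circRNA calls in model and electroacupuncture against blank, and 0 to 12 and 0 to 24 linear calls (2 and 12 at the upper ends over all kept probes). The upper ends came without electroacupuncture replicate 2, where the filter was applied again. With the probes of the main fit, leaving out that replicate gave 519 and 1184 circRNA calls, 11 and 17 linear calls (4 and 10 over all kept probes) and 3752 probes past the unadjusted p and 1.5-fold in electroacupuncture against blank. Model-minus-blank differences stayed the same, so calls there came from smaller standard errors (Rpl13a 0.47 to 0.26). In electroacupuncture against blank, Rpl13a moved from 1.32 (SE 0.47) to 1.88 (SE 0.29), and the median circRNA difference from 0.168 to 0.245. There both the differences and the standard errors changed, and how much each added to the calls was not tested.

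In model against blank the 2315 probes past the unadjusted p and 1.5-fold became 783 with normexp on median signals, 1229 with the deposited values and 1515 with the scan day block. In electroacupuncture against model the 496 became 329 with quantile normalization, 59 with normexp, 94 with the deposited values, 182 with probes above background on all 9 arrays, 1198 with array weights and 783 without the earlier scan day. In electroacupuncture against blank the 1992 became 366 with normexp, 768 with the deposited values, 995 with probes above background on all 9 arrays, 3925 with array weights and 1125 without the earlier scan day. Leaving out 1 array gave 1499 (model replicate 2) to 3245 (electroacupuncture replicate 2), 191 (model replicate 1) to 826 (electroacupuncture replicate 1) and 1126 (electroacupuncture replicate 1) to 4304 (electroacupuncture replicate 2), while 1505 and 1248 were left without blank replicate 1 in the comparisons with blank. The cause was not tested. The correlation of the first 2 comparisons was -0.702 to -0.161 in the other settings and -0.633 to 0.119 when 1 array was left out, and only the fits without electroacupuncture replicate 2 changed its sign (0.0775 with the probes of the main fit).

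Samples share only a replicate number. With the number as a block, 0 circRNA probes were called in each comparison and the unadjusted counts were 1935, 493 and 1649. Deviations of same-numbered arrays from their group means correlated at -0.524 to 0.0978. Of the same-numbered pairs, only blank replicate 1 with model replicate 1 was a best match by number. Signal over background limited the dim probes, since blank replicate 2 had 59.2% of circRNA probes well above background. No alternative was run for rno_circ_011971 or the host gene lists, which have no value here.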

Other observations

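The tests of signal distribution and of label for the second electroacupuncture array, all tests of the share of higher probes, and the test of a common shift of linear transcripts were chosen after their results were seen. The splits of the arrays, the scan day and the array scale were tested as set out beforehand. Quantile normalization was also set out beforehand, but not its use for the share of higher probes. Beyond the comparisons, some linear transcripts were well above background on few arrays. Gdnf, a growth factor for dopaminergic neurons, Nlrp3, an inflammasome sensor, and Magoh, a part of the exon junction complex, were so on 0 blank arrays, 1 model array and 1 electroacupuncture array each. The same counts held for Enpp1, Pld1, Napepld and Nat1. Of circRNA probes, 95.6% were well above background in model replicate 2 and 98.9% in electroacupuncture replicate 1, the highest shares of their groups. Such counts may therefore follow the signal of single arrays, which was not tested. Cdh2, a neuronal adhesion molecule, was so on 0, 2 and 1, and Lhcgr, a gonadotropin receptor, on none of the 9.

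Electroacupuncture replicate 2 lay with the blank arrays on the first principal component. On a scale where the blank mean is 0 and the mean of the other 5 occluded arrays is 1, it lay at -0.0267. With quantile normalization and probes above background on all arrays it lay at -0.251, and within the later scan day at -0.179, which argues against signal distribution, dim probes or scan day as the cause. Its highest rank correlation with a blank array was 0.915, below the 0.94 to 0.982 among blank arrays but not by more than their range. Its second component of -51.7 (10.5 to 24.3 in blank arrays) and its Dlg4 signal of 2.49 (mean 0.17, SD 0.20 in blank arrays) speak against a blank sample under this label, but that axis was fitted with the array in it and Dlg4 was picked after its value was seen, so with 0.915 beside 3 blank arrays a wrong label stays open, and a milder occlusion or a response to stimulation in that rat was not tested.

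Electroacupuncture tissue had more higher than lower circRNA probes past the unadjusted p and 1.5-fold, 93.8% against model and 76.5% against blank. Among the 3766 brightest probes the share against model was 48.3% of 29, but among the 3765 probes of middle signal it was 87.5% of 88. Among probes well above background on all 9 arrays it was 85.2% of 182. Whether signal near background accounts for that excess therefore stays open. Against blank the brightest probes gave 33.2%, which is on the other side of an even split. Probes well above background on all 9 arrays gave 51.4% there, and dim signal stays open in that comparison as well. Quantile normalization gave 54.1% against model and 52.2% against blank, but it makes the arrays' distributions equal and so largely sets the balance itself, and the scaling as a cause stays untested. No biological explanation was tested.

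Linear transcripts such as Rpl13a, Ldha and Pdk3 differed between model and blank in the means. The median difference of the 35 probes was 0.36, and 10000 random sets of circRNA probes of like signal had a median of 0.04 with a central range of -0.19 to 0.29, which argues against a shift of the array scale, although the median was 0.01 with normexp on median signals. The SD of the differences was 2 times their median standard error, with a bootstrap interval of 1.41 to 2.46, so one common shift of all linear transcripts, from less digestion or a lower yield of circular RNA, cannot be told apart from changes of single transcripts. The array medians of the linear probes did not separate model from blank by an exact two-sided permutation test (p = 0.2, where the smallest possible is 0.1). A change of these transcripts with occlusion stays open as a hypothesis.

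With 3 arrays against 3 there are 10 splits, too few to exclude chance at a share under 0.05. In model against blank 1 of the 10 splits gave as many as the real 2315 probes past the unadjusted p and fold, the real one itself, and the highest other had 462. In electroacupuncture against blank it was also 1, with 1992 and a highest other of 1619. In electroacupuncture against model 5 splits gave 496 or more, and the highest other had 1927, which points to a structure of the arrays other than the groups. That split set model replicate 2 with electroacupuncture replicates 1 and 3, the 3 of these 6 arrays with the highest 75th percentiles. They were 189.7, 186.3 and 137.4, against 106.5, 75.52 and 94.93 in model replicates 1 and 3 and electroacupuncture replicate 2. Whether array signal set that count was not tested. Of the splits with more than 496, those with 811 and 861 put both arrays of the earlier scan day on the same side. Those with 1927 and 1011 put them on opposite sides, and the count with scan day as a block was 474. For circRNA and linear calls, where the real count was 0, all 10 splits gave as many by definition, and the highest other was 0 except for 1 linear probe in electroacupuncture against blank.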
